A study of Mus musculus with 24 samples.

How the data were processed

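The samples were left ventricles of 24 male mice, 6 in each of 4 groups, and each ventricle gave 1 array. According to the labels, the mice carried either no transgene (CON) or an inducible, cardiomyocyte-specific transgene for the glucose transporter GLUT4 (mG4H). They received either citrate buffer (VEH) or streptozotocin (STZ), a toxin of pancreatic beta cells, at 55 mg per kg on each of 5 consecutive days. The labels place transgene induction 2 weeks after STZ and harvest 2 weeks after induction. The labels also state that sibling mice were present among the groups, without saying which mice they were.

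Per the labels, total RNA was labelled with Cy3 and hybridised to 1-colour Agilent arrays, and the submitters' processing notes name Agilent Feature Extraction and limma. Each array file lists 62976 spots. Per the file headers, the processed signal is a spot's intensity after background subtraction and detrending within the array, and it was not scaled between arrays. The deposited files also hold the raw spot intensity and the local background intensity, which served in the alternative background corrections. The headers place the probes on the mouse genome build mm9. No genome sequence or transcript annotation was used here, so probes were not assigned to exons or untranslated regions.

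The log2 processed signal was reduced by the log2 of each array's 75th percentile over its 59305 gene spots, so that a value of 0 is the array's 75th percentile. Spots that the software marked as outliers were left out, and repeated spots of a probe were averaged, which gave 55681 probes for 36413 gene names. A probe was kept when it was well above background, by the software's own mark, on at least 6 of the 24 arrays, which left 39766 probes. The probe with the highest mean over all arrays stood for its gene name, which left 28235 genes, 15626 of them named by a gene symbol. Missing values made up 0.083% of these. Of the 33064 probes with a RefSeq accession, 26413 were found in the reference table of symbols, and 3093 of those carry another current symbol there. Gene names are printed as the arrays give them.

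All 24 arrays were fitted together with limma 3.58.1 in R 4.3.3, with a mean for each group and no covariate. The 5 contrasts were STZ against VEH in each genotype, mG4H against CON under each treatment, and the difference between the STZ effects. Tests were two-sided, and p was adjusted by the Benjamini-Hochberg method over all genes, with a threshold of 0.05. Effects are given as log2 fold changes with the standard error (SE) from limma. A fold against a group that was below the background mark on all of its arrays is a lower bound against the lowest signal that each array marked as above background. In all, 38 gene lists, 24 of pathways and 14 of cell types, were tested with limma's camera at a preset correlation of 0.01. The same test was then run with the correlation between genes estimated from the data. Of the 746 list genes, 729 were measured. Blood glucose and body weight were compared with exact permutation tests, two-sided, over all 924 splits of 6 against 6 mice. Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9 read the files and drew the plots.

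The groups, the contrasts, the gene lists, the test for each result and the rule for naming genes were fixed before the data were examined. The rule named the 10 highest and the 10 lowest log2 fold changes among genes past the threshold that have a symbol and were well above background on all 6 arrays of at least 1 compared group. It added up to 4 members past the threshold from each list described, the 5 smallest p values where no gene passed, and Slc2a4, the gene for GLUT4, in every contrast. Of the genes this rule names, 2 are not reported here. Exact permutation tests of list means over arrays, single-slide fits and a fit without slide 4 were added after the data were seen.

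The alternatives tried were quantile normalization, median scaling, normexp background correction, looser and stricter filters, the mean of all probes, each probe on its own, and separate fits of each pair of groups. Further alternatives were array weights, a trended robust prior, blocks for slide, scan day and replicate number, body weight as a covariate, stricter thresholds, and leaving out each array in turn. On simulated data with 50 changed genes at each size, a true log2 change of 1 was called for 42% to 66% of genes and a change of 3 for 90% to 100%, depending on the contrast. Between 3.12% and 7.38% of the calls were false. A simulated list shift of 0.3 was called, and 0 of the 37 unshifted lists were. These simulations drew every gene independently and held no slide effect. They therefore do not measure false calls of genes or lists in real arrays, where genes vary together. No sample was left out.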

Results

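Left ventricular RNA of 24 mice was measured on 1-colour microarrays, 6 mice in each of the groups CON VEH, CON STZ, mG4H VEH and mG4H STZ. CON mice were controls, mG4H mice carried the inducible cardiac GLUT4 transgene, VEH is the buffer and STZ the beta cell toxin streptozotocin. The series asks what glucose delivery into the heart muscle does to the diabetic heart. The 75th percentile of the processed signal was between 370 and 583 per array, and 58.5% to 76.3% of spots were well above background. The number of arrays limits the precision. Slides 1 to 3 held 1 or 2 mice of every group, while slide 4, scanned on the other day, held only replicate 3 of CON VEH and of mG4H VEH. The first principal component took 42.8% of the variance, and 86.7% of it lay between slides. The second took 13.7%, of which 31.9% lay between treatments.

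Mice given STZ were severely hyperglycaemic in both genotypes. Mean blood glucose at 4 weeks was 140.7 ± 19.8 (SD, n = 6) in CON VEH and 600.8 ± 0.408 in CON STZ, by an exact permutation test with adjusted p = 0.00577 over 8 comparisons. It was 139.3 ± 7.69 in mG4H VEH and 553.8 ± 51.9 in mG4H STZ, with the same adjusted p. In both contrasts every STZ mouse lay above every vehicle mouse, and the raw exact p of 0.00216 is the smallest that 924 splits can give. All 6 CON STZ values were 600 or 601, and so were 3 mG4H STZ values, at 601. The labels give neither a unit nor the upper limit of the measurement. If 600 or 601 is that limit, the STZ means are lower bounds, and their SDs and the genotype difference under STZ are those of capped values. The genotypes differed in glucose by -1.33 under vehicle (exact permutation test, adjusted p = 0.898) and by -47.0 under STZ (adjusted p = 0.242). Body weight, also without a stated unit, was 30.85 ± 3.07 in CON VEH and 25.6 ± 2.30 in CON STZ, a drop that passed the exact permutation test (adjusted p = 0.00577). Weight was 27.3 ± 2.25 in mG4H VEH and 24.7 ± 2.35 in mG4H STZ (exact permutation test, adjusted p = 0.125). The genotypes differed in weight by -3.55 under vehicle (adjusted p = 0.0909) and -0.9 under STZ (adjusted p = 0.591) in the same exact test.

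The first comparison asked what STZ diabetes did to the control heart. Of 20 measured targets of the fatty acid receptor PPAR alpha outside beta-oxidation, 11 rose in the CON STZ ventricle and 0 fell, and the list kept its call with an estimated correlation (adjusted p = 0.0112). The natriuretic peptide genes Nppa and Nppb and the matrix genes Ctgf and Timp1 also rose, and the ketone enzyme genes Oxct1 and Bdh1 fell. The lists of extracellular matrix, called higher, and of mitochondrial ribosomes and of ketone and branched-chain amino acid catabolism, called lower, lost their calls with an estimated correlation (adjusted p = 0.203, 0.154 and 0.176). Slc2a4, which encodes the insulin-responsive glucose transporter GLUT4, fell by 0.58 ± 0.16 (SE) on the log2 scale, 1.49-fold (adjusted p = 0.0436). In all, 1117 genes passed the threshold, 469 higher and 648 lower, and 227 of them differed by at least 2-fold.

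Cyp1a1, a cytochrome P450 induced through the aryl hydrocarbon receptor, was below the background mark in 6 of 6 vehicle mice and above it in 6 of 6 STZ mice, at least 9.17-fold higher (adjusted p = 0.00046). Acot1, a cytosolic acyl-CoA thioesterase, rose 7.16-fold, from 3.27 ± 0.22 (SD, n = 6) in CON VEH to 6.11 ± 0.48 in CON STZ, on the log2 scale against the array's 75th percentile (adjusted p = 4.67e-06). Its probe lies on chromosome 12 at 85358561 to 85358620 of mm9, and all 6 STZ mice lay above all 6 vehicle mice. Angptl4, a secreted inhibitor of lipoprotein lipase, rose 5.58-fold (adjusted p = 0.000115). Acot5, a peroxisomal acyl-CoA thioesterase, had a log2 fold change of 2.34 on its brighter probe and -0.012 on its other probe. Nppa, the atrial natriuretic peptide gene, rose 5.14-fold (adjusted p = 0.00293). Clec4d, a lectin receptor of myeloid cells, rose by 2.29 on the log2 scale, Serpina3n, an acute-phase protease inhibitor, by 2.23, and Adam8, a metalloprotease of leukocytes, by 2.18. Mc2r, the corticotropin receptor, was below the background mark in every vehicle mouse and at least 2.00-fold higher in STZ mice.

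**Figure D1:**
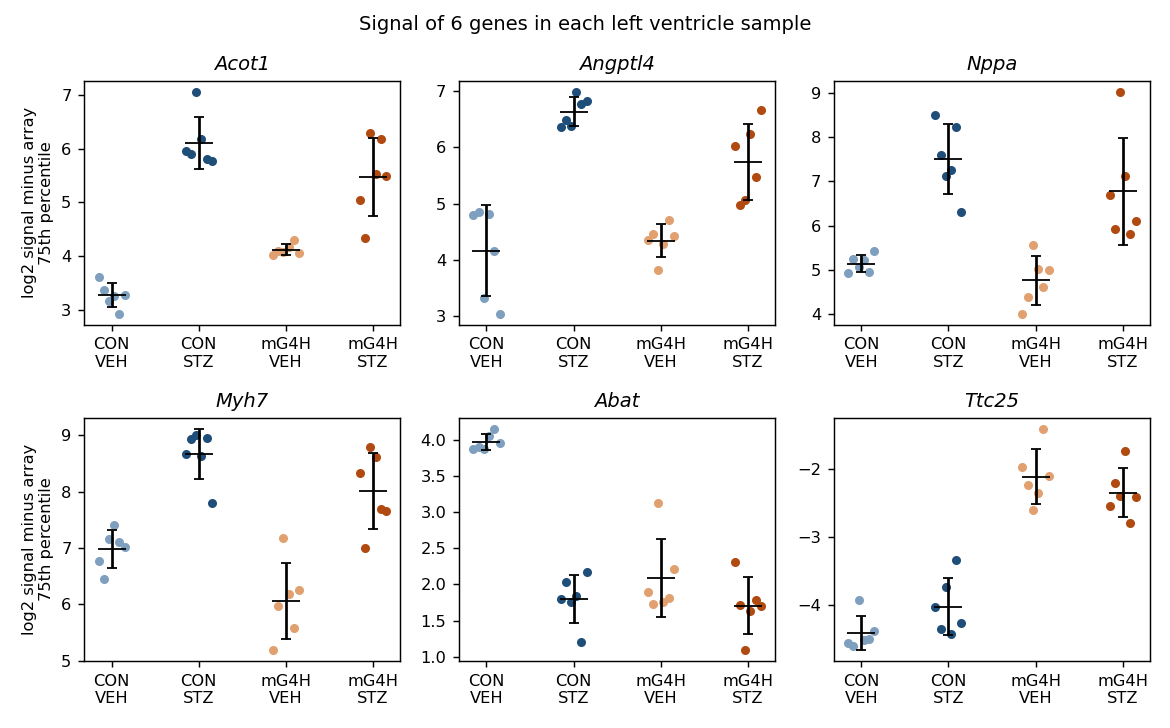
Log2 processed signal minus the array's 75th percentile for 6 genes, with 1 point per mouse, the group mean as a line and the SD as bars (n = 6 per group). For Acot1 the 6 CON STZ values, from 5.76 to 7.05, all lie above every vehicle value.

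The lowest change belonged to Tmprss4, a transmembrane serine protease, which was 6.97-fold lower (adjusted p = 0.00015). Abat, the mitochondrial transaminase that degrades GABA and beta-alanine, was 4.49-fold lower (adjusted p = 1.15e-05). Its probe lies on chromosome 16 at 8621576 to 8621635, and its signal went from 3.97 ± 0.11 (SD, n = 6) to 1.80 ± 0.33. Mmp13, an interstitial collagenase, had a log2 fold change of -2.36 and was above background in 4 of 6 STZ mice. Foxo6, a FoxO transcription factor, changed by -1.99, with -1.11 on its other probe, Mylk4, a myosin light chain kinase, by -1.84, and Lingo3 by -1.86. The phospholipase gene Pla2g4e changed by -2.03 and was above background in 4 of 6 STZ mice. Klra6, a lectin-like receptor of the natural killer cell family, changed by -2.06 and was above background in 2 of 6 STZ mice. Igfbpl1, an insulin-like growth factor binding protein relative, changed by -1.86 and was above background in 1 of 6. The sizes of these changes rest in part on signals at background. Slc2a4 was read by 10 spots of a probe on chromosome 11 at 69756073 to 69756132. Its group means were 6.73 ± 0.15 in CON VEH and 6.16 ± 0.31 in CON STZ.

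Of the 20 PPAR alpha targets, 11 rose and 0 fell, and 15 rose when adjusted over the list alone. Their mean log2 fold change was 1.14 (adjusted p = 2.79e-23), 1.12 with slide as a block and 1.12, 0.92 and 1.28 within slides 1, 2 and 3. It was the only list of this contrast to keep its call with an estimated correlation (adjusted p = 0.0112). It includes Pdk4, the kinase that switches off pyruvate dehydrogenase, which rose 4.03-fold (adjusted p = 7.17e-05). Of 25 fatty acid oxidation enzymes, 8 rose and 17 did not pass, and 14 rose and 1 fell when adjusted over the list alone. Decr1, dienoyl-CoA reductase, rose by 0.70, Cpt1a, which brings fatty acids into mitochondria, by 0.66, Ech1 by 0.62 and Hadha, of the trifunctional protein, by 0.54. The list mean was 0.28 (adjusted p = 1.37e-09; adjusted p = 0.294 with an estimated correlation), 0.28 with the slide block and 0.33, 0.21 and 0.29 within slides. Of 23 genes of glucose uptake and glycolysis, 5 fell and 0 rose, while 7 fell and 1 rose when adjusted over the list alone. Besides Slc2a4 these included Hk2, the insulin-regulated hexokinase, at -0.77, Pfkfb2, the cardiac regulator of phosphofructokinase, at -0.66, and Eno3, muscle enolase, at -0.44. The list mean was -0.15 (adjusted p = 0.00176; adjusted p = 0.294 with an estimated correlation), -0.14 with the slide block and -0.081, -0.069 and -0.20 within slides.

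Of 23 genes of ketone and branched-chain amino acid catabolism, 5 fell and 0 rose, and 15 fell when adjusted over the list alone. Oxct1, the enzyme that activates ketone bodies for oxidation, was 1.80-fold lower (adjusted p = 0.000187), and Bdh1, hydroxybutyrate dehydrogenase, was 2.33-fold lower (adjusted p = 0.0132). Dbt and Bckdhb, subunits of the branched-chain keto acid dehydrogenase, changed by -0.70 and -0.64. The list mean was -0.38 (adjusted p = 4.63e-12; adjusted p = 0.176 with an estimated correlation), -0.36 with the slide block and -0.29, -0.41 and -0.36 within slides. Of 13 genes of pyruvate oxidation, Pdk4 rose and Pdp2, a phosphatase that activates pyruvate dehydrogenase, fell by 0.86 on its brighter probe, with -0.067 on the other probe. The pyruvate list was called lower (adjusted p = 0.0431; adjusted p = 0.464 with an estimated correlation), with a median of -0.22 and a mean of -0.011, and its mean was 0.044 on slide 1 and negative on slides 2 and 3. In the glucose-responsive Mondo/ChREBP list, 2 of 11 genes rose, Txnip, an inhibitor of thioredoxin and glucose uptake, by 1.18 and Klf10, a zinc finger factor, by 0.80, with 2 higher and 2 lower when adjusted over the list alone. That list had a mean of 0.28 (adjusted p = 0.0342; adjusted p = 0.294 with an estimated correlation) and 0.26 with the slide block. In the hexosamine, polyol and pentose phosphate list, 3 of 18 genes rose and 5 rose when adjusted over the list alone, although the list itself did not pass (adjusted p = 0.0849). They were Gfpt2, which opens the hexosamine pathway, at 1.02, Khk, fructokinase, at 0.42, and G6pdx, glucose-6-phosphate dehydrogenase, at 0.31.

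**Figure D2:**
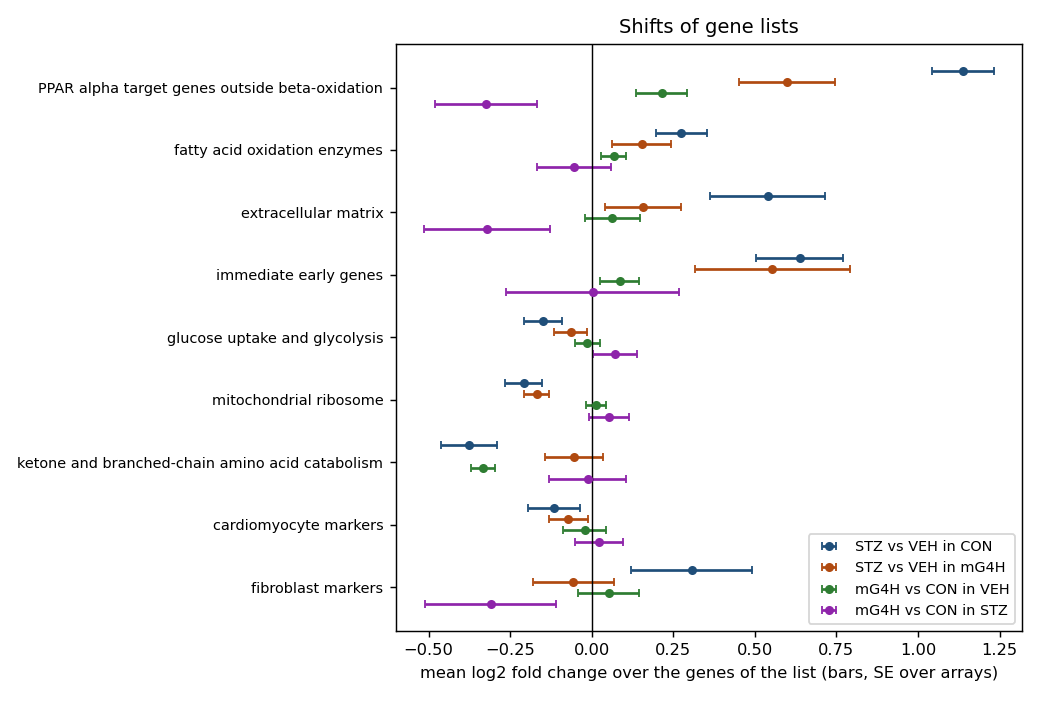
Mean log2 fold change of 9 gene lists in 4 contrasts, with bars for the SE over arrays (n = 6 per group). The PPAR alpha targets are highest in the STZ contrast of CON, at 1.14, and ketone and branched-chain amino acid catabolism sits at -0.38 there and at -0.33 for mG4H against CON under vehicle.

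Of 58 mitochondrial ribosome genes, 3 fell and 23 fell when adjusted over the list alone, Mrps27 at -0.34, Mrps12 at -0.33 and Mrpl12 at -0.33. The list mean was -0.21 (adjusted p = 2.36e-20; adjusted p = 0.154 with an estimated correlation), -0.21 with the slide block and -0.11, -0.19 and -0.27 within slides. Of 36 nuclear genes for complex I, 2 fell, Ndufs8 by 0.42 and Ndufs4 by 0.31, and the same number fell when adjusted over the list alone. That list mean was -0.14 (adjusted p = 4.98e-07; adjusted p = 0.418 with an estimated correlation) and -0.12 with the slide block. In the TCA cycle, 1 of 20 genes fell, Pcx, the pyruvate carboxylase that refills the cycle, by 1.03, and 2 fell when adjusted over the list alone (list mean -0.15, adjusted p = 0.000253; adjusted p = 0.418 with an estimated correlation). In mitochondrial biogenesis and dynamics, 1 of 24 genes fell, the nuclear receptor gene Esrrg, by 0.28, and 6 fell when adjusted over the list alone (mean -0.14, adjusted p = 0.000592; adjusted p = 0.294 with an estimated correlation). Among 42 genes of complexes II to V no member passed limma's test over all genes, and the list mean was -0.10 (adjusted p = 0.000187; adjusted p = 0.495 with an estimated correlation), -0.09 with the slide block and -0.016 on slide 2.

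Genes of cardiac stress were raised in part. Myh7, the slow myosin heavy chain of the fetal heart, rose 3.21-fold (adjusted p = 0.00329), and Nppb, the B-type natriuretic peptide, by 1.35 (adjusted p = 0.00431). Kcnd2, a potassium channel of early repolarisation, was 2.00-fold lower. In the list of contractile, calcium handling and fetal genes 4 of 30 rose and 2 fell, against 5 and 3 when adjusted over the list alone. That list was not called (adjusted p = 0.853), and its median of -0.034 and mean of 0.15 differ in sign. Of 32 extracellular matrix genes, 8 rose and 0 fell, and 12 rose when adjusted over the list alone. Ctgf, a matricellular growth factor, rose 4.08-fold (adjusted p = 0.00533), Timp1, an inhibitor of metalloproteases, by 1.88, Spp1, osteopontin, by 1.63, from a signal above background in 5 of 6 CON VEH mice, and Postn, periostin, by 1.26. The matrix list mean was 0.54 (adjusted p = 2.13e-09; adjusted p = 0.203 with an estimated correlation), 0.54 with the slide block and 0.39, 0.84 and 0.36 within slides. Of 23 immediate early genes, 5 rose and 7 rose when adjusted over the list alone, among them Atf3 by 1.59, Fos by 1.31, Myc by 1.24 and Ier3 by 0.74. This list mean was 0.64 (adjusted p = 3.95e-10; adjusted p = 0.219 with an estimated correlation), 0.65 with the slide block and 0.35, 0.69 and 0.89 within slides. Of 27 genes of the unfolded protein and integrated stress response, 6 rose, while 7 rose and 1 fell when adjusted over the list alone. Mthfd2, a mitochondrial folate enzyme, rose by 1.69, Gdf15, a stress cytokine, by 1.16, Asns, asparagine synthetase, by 0.81 and Psat1, of serine synthesis, by 0.65. The stress list mean was 0.26 (adjusted p = 0.0154; adjusted p = 0.368 with an estimated correlation) and 0.26 with the slide block.

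Among fibroblast markers 1 of 12 rose, Mfap5, a microfibril protein, by 0.84, and the list mean was 0.31 (adjusted p = 0.00119; adjusted p = 0.294 with an estimated correlation), with 0.24, 0.53 and 0.036 within slides. Macrophage and monocyte markers had a mean of 0.26 (adjusted p = 0.00406; adjusted p = 0.379 with an estimated correlation), and their only called member, Itgam, rose by 0.48 on 1 probe while its other 2 probes gave -0.091 and 0.018. The macrophage mean was 0.073, 0.73 and 0.033 within slides. Adipocyte markers had a mean of 0.58 (adjusted p = 8.44e-05; adjusted p = 0.125 with an estimated correlation), 0.57 with the slide block, and 2 of 10 rose, Lipe, hormone-sensitive lipase, by 1.11 and Cidea, a lipid droplet protein, by 1.04. Heart muscle itself can express Lipe and Cidea. Cardiomyocyte markers had a mean of -0.12 (adjusted p = 0.0144; adjusted p = 0.436 with an estimated correlation), with 1 of 13 lower, Ckm, muscle creatine kinase, at -0.47. With the slide block the cardiomyocyte mean was -0.084. Atrial cardiomyocyte markers, which include Nppa, had a mean of 0.46 and were not called by camera (adjusted p = 0.082), but passed the exact permutation test on array means (adjusted p = 0.0247), with 0.24, 0.65 and 0.54 within slides. Nppa was the only 1 of the 8 atrial markers past limma's test. In the mG4H heart the atrial mean after STZ was -0.22 (exact permutation test, adjusted p = 0.844).

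In all, 27 of 38 lists were called by camera, 12 higher and 15 lower, and 13 by an exact permutation test on the arrays' list means. The directions were 14 and 12 with normexp, 14 and 13 with median scaling, 13 and 12 with slide as a block, 15 and 13 without CON VEH replicate 6, 12 and 9 without CON STZ replicate 5 and 8 and 14 without CON STZ replicate 4. Replicates decided part of these counts. The number of genes was 636 without CON STZ replicate 1, 732 without CON STZ replicate 5, 705 without CON VEH replicate 3, 75 with median scaling, 2426 with array weights, 168 with body weight as a covariate and 1399 with slide as a block. Slc2a4 fell short of the threshold with several single arrays left out, to an adjusted p of 0.114 and a log2 fold change of -0.47 without CON STZ replicate 5. With slide as a block Esrrg, Asns, Psat1, Spp1, Postn and Mfap5 missed the threshold, at adjusted p = 0.0518 to 0.079.

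The next comparison asked for the STZ effect in hearts with the GLUT4 transgene. The diabetic mG4H heart showed higher Myh7, Nppa and Acot1, as the diabetic control heart did, and lower Tmprss4 and Igfbpl1. Of these, Nppa (adjusted p = 0.0623), Tmprss4 (adjusted p = 0.0734) and Igfbpl1 (adjusted p = 0.0551) missed the threshold with slide as a block. In all, 75 genes passed, 28 higher and 47 lower, and 27 of them differed by at least 2-fold. Myh7 rose 3.88-fold (adjusted p = 0.00869). Acot1 rose 2.57-fold, from 4.12 ± 0.10 (SD, n = 6) to 5.48 ± 0.73 (adjusted p = 0.0241). Nppa rose 4.01-fold (adjusted p = 0.0494). Cldn15, a claudin of cell junctions, rose 3.24-fold, and H19, an imprinted noncoding RNA, 2.25-fold, a log2 fold change of 1.17 where its 6 other probes had 0.29 to 1.26. Fam183b rose by 1.33 on the log2 scale, Cela1, an elastase gene, by 1.16, from a signal above background in 4 of 6 mG4H VEH mice, Rpp25, an RNase P subunit, by 1.03, and Rbp7, a retinol binding protein, by 0.93. Plekhh1 was 3.38-fold lower, Tmprss4 changed by -1.73 and Igfbpl1 by -1.53, with Igfbpl1 above background in 3 of 6 mG4H STZ mice. Grin3b, a glutamate receptor subunit, changed by -1.25, Cacna1g, a T-type calcium channel, by -1.24, with -0.82 on its other probe, and Lgi3, a secreted leucine-rich repeat protein, by -1.23. Mdga1 changed by -1.31, the crystallin gene Crybb1 by -1.30, the steroid transporter subunit Osta by -1.10 and the homeobox gene Cux2 by -1.03. Slc2a4 had a log2 fold change of -0.18 (adjusted p = 0.715).

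Camera at its preset correlation called gene lists in the mG4H heart too, with few single members past the threshold, and chance was not excluded for these calls. Of 20 PPAR alpha targets, 2 rose and 11 rose when adjusted over the list alone, with a list mean of 0.60 (adjusted p = 8.89e-10; adjusted p = 0.426 with an estimated correlation). That mean was 0.55 with the slide block and 0.62, 0.25 and 0.76 within slides. None of the 58 mitochondrial ribosome genes passed limma's test over all genes, 8 fell when adjusted over the list alone, and the list mean was -0.17 (adjusted p = 7.37e-15; adjusted p = 0.527 with an estimated correlation). The ribosome mean was -0.16 with the slide block and -0.13, -0.16 and -0.24 within slides. The 23 immediate early genes had a mean of 0.55 (adjusted p = 3.56e-08; adjusted p = 0.671 with an estimated correlation), 0.52 with the slide block and 0.54, 0.33 and 0.68 within slides. Among 19 circadian clock genes Hlf, an output factor of the clock, fell by 0.44 over all genes, while 8 rose and 1 fell when adjusted over the list alone. The clock list was called higher with a mean of 0.46 (adjusted p = 0.0354; adjusted p = 0.671 with an estimated correlation) and 0.44 with the slide block. Insulin signalling and FoxO targets, 21 genes, had a mean of 0.46 (adjusted p = 3.76e-05; adjusted p = 0.671 with an estimated correlation). Fatty acid oxidation enzymes had a mean of 0.15 (adjusted p = 0.00347; adjusted p = 0.673 with an estimated correlation), but -0.048 on slide 2. Ketone and branched-chain amino acid catabolism had a mean of -0.055 and was not called. In all, camera called 18 lists, 7 higher and 11 lower, and 0 with an estimated correlation. The directions were 7 and 6 with slide as a block, 6 and 6 without mG4H STZ replicate 4, 4 and 15 without replicate 5 and 3 and 10 without replicate 6. An exact permutation test on the arrays' list means called 0 of 38 lists here and 13 in the CON contrast. The smallest p that this test can give is 0.00216, reached here by the mitochondrial ribosome alone, and adjusted over the lists it was 0.0821. In CON several lists shared that p, which brought it to 0.0117. The exact test thus could not call a lone list, and its 0 does not show that no list moved.

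With slide as a block Fam183b, H19, Cela1, Rpp25, Rbp7, Cacna1g, Osta and Cux2 missed the threshold too, at adjusted p = 0.0525 to 0.0765. The count was 48 with that block, and a fit of the mG4H arrays alone called 0 genes with limma, with 2818 at an unadjusted p under 0.05. The count also rested on few mice. Without mG4H STZ replicate 2, whose Cyp1a1 signal of -7.38 lay at vehicle level, 627 genes passed, and 161 passed without CON STZ replicate 3. Every other array that moved the count by over 1.5 times lowered it. The lowest, 17, came without mG4H STZ replicate 3 or mG4H VEH replicate 1. It was 18 without mG4H VEH replicates 4 or 5, 19 and 20 without replicates 6 and 2, and 42 without replicate 3. It was 29, 34 and 42 without mG4H STZ replicates 4, 5 and 1, 32 and 34 without CON STZ replicates 2 and 5, and 32 to 36 without any 1 CON VEH mouse.

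The STZ effects of the genotypes overlapped. Of the 1117 genes called in CON and the 75 called in mG4H, 69 were called in both, 25 higher and 44 lower, against 0.465 and 1.08 by chance, and 0 in opposite directions. Of the CON genes, 97.9% had the same sign in mG4H. Across all 28235 genes, which are not independent replicates, the effects had a Pearson r of 0.61 and a Spearman rho of 0.54. The jackknife SE of r over arrays was 0.21. Slide 4 held 1 vehicle mouse of each genotype and 0 STZ mice, so its slide effect enters both STZ contrasts in the same direction. The chance counts do not take this into account, and the overlap and r were not computed with slide as a block.

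**Figure D3:**
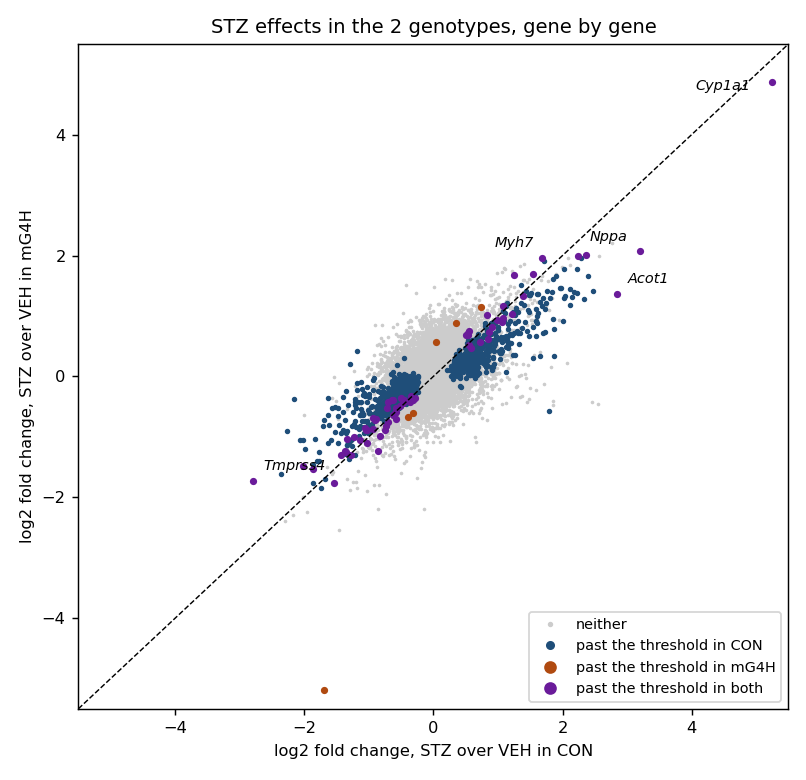
Log2 fold change of each of 28235 genes for STZ against VEH in CON (horizontal) and in mG4H (vertical), with the dashed line of equal effects. The 69 genes past the threshold in both genotypes, in purple, lie in the 2 quadrants of equal sign.

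Whether the STZ effect itself differed between the genotypes was the central question of the design. No single gene passed limma's test of that difference. The count of genes was 0, with 501 at an unadjusted p under 0.05 in limma's test against 1412 expected by chance, and 783 with slide as a block. The genotype contrasts also lay below 1412, at 811 under vehicle and 1003 under STZ. The fit shared 1 spread per gene over all groups. Their median SDs were 0.2382 in CON VEH and 0.2164 in mG4H VEH, against 0.3286 in CON STZ and 0.3855 in mG4H STZ. With only the 2 compared groups fitted, the genotype counts were 1674 under vehicle and 468 under STZ. The shortfall under vehicle thus came with the shared spread, while under STZ it remained. In the common fit the difference had fewer small p values than chance gives. The absence of calls therefore does not show that the STZ effects are equal. The smallest adjusted p of the difference was 0.15. It belonged to Abat, whose STZ effects differed by 1.79 ± 0.30 (SE). Its signal was 2.09 ± 0.54 (SD, n = 6) in mG4H VEH and 1.71 ± 0.39 in mG4H STZ. Fgf21, a fasting hormone induced by PPAR alpha, had a difference of -2.36 ± 0.43 (adjusted p = 0.228). Grin2c, a glutamate receptor subunit, had 1.61 (adjusted p = 0.311), Acot4, a peroxisomal thioesterase, -0.78 (adjusted p = 0.606), and Cib3, a calcium-binding protein, 1.49 (adjusted p = 1). Abat, Grin2c and Cib3 were also called lower in mG4H than in CON under vehicle, and that lower vehicle level enters their difference. Slc2a4 had a difference of 0.40 (adjusted p = 1).

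Camera called 12 lists for the difference, 2 higher and 10 lower in mG4H, and 0 with an estimated correlation. The directions were 5 and 7 with quantile normalization, 5 and 8 with the filter on all 24 arrays, 3 and 6 with slide as a block and 7 and 7 without mG4H STZ replicate 4. The STZ effect on PPAR alpha targets was smaller in mG4H by a mean of -0.54 (adjusted p = 4.58e-13; adjusted p = 0.0885 with an estimated correlation). That list lay at 0.214 in mG4H against CON under vehicle and at -0.325 under STZ, so a higher vehicle level is part of its difference. For extracellular matrix the mean difference was -0.38 (adjusted p = 8.85e-10; adjusted p = 0.2 with an estimated correlation). For ketone and branched-chain amino acid catabolism it was 0.32 (adjusted p = 2.33e-13; adjusted p = 0.143 with an estimated correlation). That list lay at -0.334 in mG4H against CON under vehicle and at -0.012 under STZ, so its difference is mostly the shift under vehicle. Fibroblast markers had -0.36 (adjusted p = 3.84e-05; adjusted p = 0.213 with an estimated correlation), with slide 3 alone at 0.23, and extracellular matrix had 0.17 on slide 3 alone. The difference in Abat passed with slide as a block (1.84, adjusted p = 0.0431), without mG4H VEH replicate 3 (adjusted p = 0.000988) and without mG4H STZ replicate 3 (adjusted p = 0.0426). It also passed with normexp and quantile normalization (adjusted p = 0.0476), a trended robust prior (adjusted p = 0.05) and array weights (adjusted p = 0.0146), where 6 genes were called.

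The comparison of genotypes under vehicle asked what the transgene did in the non-diabetic heart. The mG4H heart had higher RNA for the fat synthesis enzyme Acaca and the ketone-activating enzyme Aacs, and lower RNA for the enzymes Upb1, Abat, Gcat and Ccbl2. In all, 23 genes passed, 10 higher and 13 lower, and 11 of them differed by at least 2-fold. Ttc25, a protein of motile cilia, rose 4.95-fold (adjusted p = 4.48e-06), with its probe on chromosome 11 at 100415182 to 100415241. The log2 fold change was 2.31 on this probe and 2.73 on its other probe. Lgi3 rose by 1.30 on the log2 scale (adjusted p = 0.000933). Acaca, acetyl-CoA carboxylase, which makes malonyl-CoA, rose 2.06-fold (adjusted p = 0.000529). Impa2, an inositol phosphatase, rose by 0.76, Klf10 by 0.72, Aacs by 0.70, Ralgapa2, a regulator of Ral GTPases, by 0.63, with 0.32 to 0.64 on its 2 other probes, and Pth1r, the parathyroid hormone receptor, by 0.55. Cib3 was 4.73-fold lower (adjusted p = 4.1e-05). Upb1, an enzyme of pyrimidine breakdown that yields beta-alanine, was 4.38-fold lower (adjusted p = 0.000933), and Abat 3.68-fold lower (adjusted p = 9.54e-05). Gcat, of threonine and glycine breakdown, changed by -1.06 (adjusted p = 0.00053), and Ccbl2, a kynurenine aminotransferase, by -0.84. Grin2c changed by -1.32, Cdh16, a cadherin, by -0.82, Dcxr, a xylulose reductase, by -0.78, and Cyb5, cytochrome b5, by -0.44. Slc2a4 had a log2 fold change of -0.20 (adjusted p = 1), with means of 6.73 ± 0.15 (SD, n = 6) and 6.54 ± 0.11. Whether the transgene carries the sequence that this probe reads is not given in the sources used here, so the probe does not check the genotype labels.

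The list of ketone and branched-chain amino acid catabolism was lower in the vehicle mG4H heart, with a mean of -0.33 and 12 of 23 genes lower when adjusted over the list alone, although none passed limma's test over all genes. Its adjusted p was 5.98e-25, and adjusted p = 0.0466 with an estimated correlation, the only list of this contrast to keep its call. The mean was -0.35 with the slide block and -0.38, -0.28 and -0.30 within slides. Bdh1 had a log2 fold change of -1.02 (adjusted p = 0.378), Oxct1 of -0.55 (adjusted p = 0.0766) and Bcat2, the mitochondrial branched-chain aminotransferase, of -0.53 (adjusted p = 0.0929). PPAR alpha targets had a mean of 0.21 (adjusted p = 0.000953; adjusted p = 0.515 with an estimated correlation), 0.25 with the slide block, and 5 of 20 were higher when adjusted over the list alone. Mondo/ChREBP genes had a mean of 0.24 (adjusted p = 0.00438; adjusted p = 0.324 with an estimated correlation) and 0.25 with the slide block, with Klf10 past the threshold. In fatty acid and sterol synthesis Acaca alone of 25 genes passed, and the list mean was 0.081 (adjusted p = 0.00847; adjusted p = 0.402 with an estimated correlation). Adipocyte markers had a mean of 0.20 (exact permutation test, adjusted p = 0.458), with 0.45, 0.31 and 0.016 within slides. Mesothelial and epicardial markers had a mean of -1.07 (adjusted p = 0.000354; adjusted p = 0.476 with an estimated correlation), -0.999 with the slide block, and none of the 8 passed limma's test. In all, 9 lists were called, 7 higher and 2 lower, and an exact permutation test on array means called 0 of 38. The ketone and branched-chain list had the smallest p that this exact test can give, 0.00216. Adjusted over the lists it was 0.0821, so the test could not have called this list alone. The directions were 3 and 2 with slide as a block or without mG4H VEH replicate 6, 2 and 3 without mG4H VEH replicate 4 and 12 and 2 without mG4H VEH replicate 1. The number of genes was 13 without CON VEH replicate 3 or 4, 14 without mG4H VEH replicate 4 or 5, 15 without mG4H VEH replicate 6, 38 without mG4H STZ replicate 3, 212 with array weights and 30 with slide as a block.

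The last comparison asked what the transgene did in the diabetic heart. Ttc25 was again higher in mG4H, 3.21-fold (adjusted p = 0.00127), and few other genes passed. The 3 genes were Ttc25, an intergenic noncoding transcript on chromosome 6 at 50405629 to 50405688 that rose by 1.31 (adjusted p = 0.0185), and LOC640020, at -1.11 (adjusted p = 0.00627). The noncoding transcript and LOC640020 lie outside the rule for names and were chosen after their values were seen. All 3 were also called under vehicle, in the same direction. Slc2a4 had a log2 fold change of 0.20 (adjusted p = 1). Across all genes, which are not independent replicates, the genotype effects under vehicle and STZ had a Pearson r of 0.0701 and a Spearman rho of 0.0514.

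Under STZ, camera at its preset correlation called PPAR alpha targets and extracellular matrix lower in mG4H than in CON, with no single member past limma's test over all genes, and chance was not excluded for these calls. The PPAR alpha list had a mean of -0.33 (adjusted p = 1.03e-08; adjusted p = 0.23 with an estimated correlation), with -0.26, -0.49 and -0.23 within slides. Extracellular matrix had a mean of -0.32 (adjusted p = 4.13e-10; adjusted p = 0.23 with an estimated correlation), with -0.39, -0.72 and 0.15 within slides. Fibroblast markers had a mean of -0.31 (adjusted p = 7.54e-06; adjusted p = 0.23 with an estimated correlation), with -0.48, -0.60 and 0.16 within slides. Macrophage markers had a mean of -0.26 (adjusted p = 0.00296; adjusted p = 0.501 with an estimated correlation), with 0.28 on slide 3. Adipocyte markers had a mean of -0.19 (exact permutation test, adjusted p = 0.928), with -0.13, -0.28 and -0.17 within slides. Mitochondrial ribosome genes had a mean of 0.054 (adjusted p = 0.00212; adjusted p = 0.661 with an estimated correlation), with -0.003 on slide 1, and TCA cycle genes of 0.083 (adjusted p = 0.00431; adjusted p = 0.661 with an estimated correlation). In all, 18 lists were called, 9 higher and 9 lower, 0 with an estimated correlation and 0 by the exact permutation test on array means. The directions shifted with the settings: 2 were higher and 6 lower with median scaling, 5 and 8 with quantile normalization, and 7 and 7 with slide as a block. Without 1 array they were 2 and 5 (CON STZ replicate 1), 1 and 9 (CON STZ replicate 5), 0 and 6 (mG4H STZ replicate 5), 3 and 9 (mG4H STZ replicate 6) and 14 and 7 (mG4H STZ replicate 4). The count of genes was 12 without CON STZ replicate 3 and 5 without mG4H STZ replicate 5, and 4 with slide as a block. A fit of the STZ arrays alone called 0 genes with limma, with 468 at an unadjusted p under 0.05.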

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

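The counts over other splits of the arrays, the scores of their sides and the test of cardiomyocyte markers were chosen only after the results were seen.

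In 12 gene lists the STZ effect differed between the genotypes by the camera test of the difference, and in 0 of them with an estimated correlation. The STZ effect in mG4H minus that in CON was -0.54 for PPAR alpha targets outside beta-oxidation and -0.12 for fatty acid oxidation enzymes. It was -0.38 for extracellular matrix, -0.36 for fibroblast markers and -0.24 for macrophage and monocyte markers. Adipocyte markers had -0.40 and atrial cardiomyocyte markers -0.68. The hexosamine, polyol and pentose phosphate list had -0.095, the unfolded protein and integrated stress response -0.11 and interferon-stimulated genes -0.13. The values above 0 were 0.081 for mitochondrial biogenesis and dynamics and 0.32 for ketone and branched-chain amino acid catabolism. For the atrial list the adjusted p was 0.0144, and adjusted p = 0.213 with an estimated correlation, and its value on slide 3 alone was 0.72. In mG4H against CON the atrial list lay at 0.503 under vehicle and at -0.172 under STZ. Its vehicle means had an SD over arrays of 1.126 in mG4H and 0.242 in CON. Adipocyte markers lay at 0.203 under vehicle and -0.194 under STZ, and PPAR alpha targets at 0.214 and -0.325. The differences of these lists thus do not come from the STZ hearts alone.

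The first pattern is the smaller STZ effect in mG4H among genes called in CON, where the mG4H effect was a median of 0.62 of the CON effect, while among genes called in mG4H the CON effect was a median of 1.08 of the mG4H effect. Because genes picked by a large value in CON look smaller elsewhere, 2908 genes were picked by the mean STZ effect of both genotypes, which gave signed effects of 0.56 in CON and 0.47 in mG4H, and the difference of 0.091 had an exact permutation p of 0.523 over 853776 arrangements. With slide as a block the difference was 0.116 (p = 0.405 in 10000 permutations within slides), and it was -0.096, 0.31 and 0.034 on slides 1, 2 and 3. It was 0.0279 without mG4H STZ replicate 2 and 0.0377 without CON STZ replicate 3, so a single mouse could carry much of it. The choice of genes, the slides and a true effect of the transgene all remain open.

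The second pattern is the lower level of ketone and branched-chain amino acid catabolism genes in mG4H hearts under vehicle, with a list mean of -0.33. Slide differences are argued against by the value with slide as a block over the 12 vehicle arrays, -0.344 (p = 0.008 in permutations within slides). Fewer cardiomyocytes are argued against by the mean of the cardiomyocyte markers, -0.022 ± 0.066 (SE). Chance among these 12 mice stays open. The exact permutation p was 0.00216, the smallest that the splits can give, but adjusted over the lists it was 0.0821. The transgene itself may be the source, as a hypothesis only, since the pattern was found and tested in the same mice.

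Other splits of the arrays were drawn 100 times per contrast, the real one included, so 1 of 100 is the smallest share possible. The other splits called a median of 14 lists for STZ in CON and 12 for STZ in mG4H. Their median was 9 for genotype under vehicle, 15 for genotype under STZ and 11 for the difference. Camera at its preset correlation thus called many lists without the real grouping. For the STZ contrast in CON, 2 of 100 splits gave as many genes as the real 1117, with a highest other count of 2456. For lists, 1 of 100 gave as many as the real 27, with a highest other of 26. Within slides and with slide as a block, 2 of 100 gave as many lists as the real 25, with a highest other of 25. Such counts were rare, which argues against chance for both without excluding it, and the lead in lists was narrow. For the STZ contrast in mG4H, 2 of 100 gave as many genes as the real 75, with a highest other of 5345. Such a count was rare, but chance is not excluded, since within slides another split gave 57 genes against the real 48. For lists, 23 gave as many as the real 18, with a highest other of 28, so chance could not be excluded there either. For genotype under vehicle, 1 of 100 gave as many genes as the real 23, with a highest other of 0, which argues against chance. For lists, 52 gave as many as the real 9, with a highest other of 21, so chance could not be excluded. For genotype under STZ, 8 gave as many genes as the real 3, with a highest other of 6462, and 34 as many lists as the real 18, with a highest other of 28, so chance could not be excluded. For the difference, 100 gave as many genes as the real 0, with a highest other of 1918, and 50 as many lists as the real 12, with a highest other of 24, so chance could not be excluded there either. The splits with 2456, 5345 and 6462 genes were uneven over slides, with an imbalance of 4 arrays against 1, 1 and 0 in the real splits, but other splits as uneven called 0 genes. Drawn within slides and fitted with slide as a block, the real counts were 1399, 48, 30, 4 and 1 genes in the same order, and the highest others were 0, 57, 1, 3682 and 712. The 3682 genes came from a split of the STZ mice that was even over slides, so slides alone do not account for such counts. The mean signed STZ change over the 2908 genes differed between its sides by 0.24, a gap reached in 6 of these 100 splits of the STZ mice against a median of 0.087.

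Of 141 groups of 6 values tested for an array far from the other 5, 13 had one, 9.22%, where chance gives about 1 in 20. Each value here is the gap to the nearest other sample over the range of the group. Blood glucose of CON STZ replicate 2 had 1, since it was 600 where the other mice had 601. The 75th percentile of the signal of mG4H STZ replicate 3 had 0.645. In CON STZ replicate 3 Acot1 had 0.669 and Acot5 0.698. In CON STZ replicate 1 Adam8 had 0.808 and Cib3 0.772. Tmprss4 had 0.651 in CON VEH replicate 4, and Cux2 0.696 in mG4H STZ replicate 3. On the slide 4 arrays, Ttc25 had 0.656 in CON VEH replicate 3. In mG4H VEH replicate 3, on the same slide, Abat had 0.653, Slc2a4 0.681, Osta 0.666 and Upb1 0.813. These slide 4 arrays gave 5 of the 11 outlying values of named genes.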

How the results depend on the processing

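The fits of single slides and the fit without slide 4 were chosen after seeing the data. No named gene past the threshold turned its direction on its chosen probe under the settings tried, on single slides or with 1 array left out. These genes were picked for passing the threshold in the same arrays, so turns were unlikely from the outset. On another probe Acot5 turned from 2.34 to -0.012 and Itgam from 0.48 to -0.091 for STZ in CON. Counts moved more, and some lists turned. In the STZ contrast of CON, 883 of 1098 values of named genes kept their side of the threshold and 215 lost it, and with 1 array left out 1616 of 1896 kept it. In the STZ contrast of mG4H, 171 of 291 and 269 of 504 kept it. Under vehicle, 206 of 238 and 355 of 408 genotype values kept it, and under STZ 11 of 14 and 24 of 24. For lists, 250 of 300, 146 of 190, 67 of 90, 129 of 180 and 92 of 120 values kept their side across settings, in the order STZ in CON, STZ in mG4H, genotype under vehicle, genotype under STZ and the difference. Signal over background limits the faint genes: a gene below the background mark in a whole group has a fold that is only a lower bound. Except where a setting tests fewer genes or fewer arrays, or by its construction sets a stricter threshold, the cause was not tested.

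Median scaling called 75, 6 and 8 genes for STZ in CON, STZ in mG4H and genotype under vehicle, and 8 lists for genotype under STZ, and Slc2a4 was at -0.62 without a call for STZ in CON. The normexp correction with the 75th percentile called 0 genes with limma for genotype under STZ, with 1000 at an unadjusted p under 0.05. With quantile normalization after normexp the counts were 233 for STZ in mG4H, 46 for genotype under vehicle, 14 higher and 32 lower against 10 and 13, and 1 for the difference. With no filter 31 genes were called for STZ in mG4H, and Slc2a4 was at -0.58 in CON (adjusted p = 0.061). With the filter on all 24 arrays 125 were called for STZ in mG4H. The mean of all probes gave 43 genes for STZ in mG4H and 1 for genotype under STZ, and every probe on its own gave 36 for STZ in mG4H. Fits of only the compared groups gave 0 genes with limma for STZ in mG4H, with 2818 at an unadjusted p under 0.05, 100 for genotype under vehicle, and 0 for genotype under STZ, with 468. Array weights gave 2426, 246, 212, 15 and 6 genes in the 5 contrasts. The lowest weights were 0.227 and 0.24 for mG4H STZ replicates 5 and 3 and 0.288 for CON STZ replicate 3. Those mice had the largest mean signed STZ change over the 2908 genes, so this setting plays down the strongest responses. A trended and robust prior gave 203 for STZ in mG4H and 1 for the difference. With slide as a block 48 genes were called for STZ in mG4H and 1 for the difference, with 5 lists for genotype under vehicle. With scan day as a block 28 were called for STZ in mG4H, and Slc2a4 was at -0.58 (adjusted p = 0.0627). With replicate number as a block Slc2a4 was at -0.58 (adjusted p = 0.0909). Samples of equal number correlated between -0.6 and 0.664 after group means were removed. Slide differences were left in these values, so they cannot tell whether the numbers pair samples. With body weight as a covariate 168, 17 and 12 genes were called for STZ in CON, STZ in mG4H and genotype under vehicle, and Slc2a4 was at -0.68 (adjusted p = 0.222). Weight differed with STZ, so this fit also removes part of the treatment's effect. A threshold of 0.01 left 365, 12 and 10 genes, and a change of at least 2-fold left 227, 27 and 11. With an estimated correlation 1, 0, 1, 0 and 0 lists were called. Over the genes called in at least 1 genotype, the correlation of the STZ effects was 0.91. Those genes were picked by the same effects, which raises r, so this value is no check on the r across all genes. By medians in place of means, glucose differed by 459.0 for STZ in CON (exact permutation test, adjusted p = 0.0996) and by 419.5 in mG4H (adjusted p = 0.0779), and weight by -4.1 in CON (adjusted p = 0.0779).

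Slide 1 alone called 0 genes in the first 4 contrasts, and 7, 9, 4, 7 and 3 lists, with Slc2a4 at -0.43 for STZ in CON. Slide 2 alone called 0 genes in those contrasts, and 19 lists for the difference, with Slc2a4 at -0.51. Slide 3 alone called 0 genes in those contrasts, and 16 lists for STZ in CON, 2 and 2 for genotype under vehicle and under STZ and 3 for the difference, with Slc2a4 at -0.64. In these single-slide fits with limma, 341 to 1863 genes had an unadjusted p under 0.05 in those contrasts, fewer arrays were tested, and the lone vehicle arrays of CON on slide 2 and of mG4H on slide 3 were assumed to vary like the other groups. Without slide 4, 642 genes were called for STZ in CON, 23 for STZ in mG4H, 14 for genotype under vehicle and 1 for the difference, with Slc2a4 at -0.54. With 1 array left out the counts were 636 to 1640, 17 to 627, 13 to 38, 2 to 12 and 0 to 1 genes, the lists for genotype 5 to 14 under vehicle and 6 to 21 under STZ, and Slc2a4 -0.63 to -0.47 for STZ in CON. The arrays that moved the counts of genes are named with the counts. The lists under vehicle were 5 without mG4H VEH replicate 4 or 6 and 14 without replicate 1, and under STZ 6, 7 and 10 without mG4H STZ replicate 5, CON STZ replicate 1 and CON STZ replicate 5.

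With 1 array left out, contractile, calcium handling and fetal genes were at 0.12 to 0.18 for STZ in CON, where the test's sign turned while the mean did not, at 0.14 without CON VEH replicate 2 or 5 or CON STZ replicate 2 or 4, and on slide 3 at 0.15. Under STZ, fatty acid oxidation enzymes were at -0.11 to 0.014 for the genotypes, the upper value without mG4H STZ replicate 2, and insulin signalling and FoxO targets at -0.02 to 0.31, the lower value without mG4H STZ replicate 5. The single-slide values that follow come from separate fits of each slide and can differ slightly from the within-slide means given above. On slide 1 the values were 0.053 for glycogen and 0.054 for the TCA cycle (STZ in mG4H), 0.003 for fatty acid oxidation and -0.002 for the mitochondrial ribosome (genotype under STZ) and 0.072 for the unfolded protein response (difference). On slide 2 they were -0.016 for complexes II to V and 0.004 for mitochondrially encoded genes (STZ in CON), where the test's sign turned. For STZ in mG4H they were -0.048 for fatty acid oxidation, 0.047 for antioxidant defence, 0.15 for interferon-stimulated genes and 0.36 for erythrocyte and platelet markers. For genotype under STZ they were -0.13 for insulin signalling, -0.35 for the circadian clock and 0.075 for interferon, and for the difference 0.038 for mitochondrial biogenesis and 0.38 for interferon. On slide 3 adipocyte markers were at 0.016 for genotype under vehicle. For genotype under STZ that slide gave -0.017 for fatty acid oxidation, -0.034 for glycogen, 0.008 for the hexosamine list, 0.007 for the unfolded protein response, 0.15 for extracellular matrix, 0.16 for fibroblast and 0.28 for macrophage markers. For the difference it gave -0.038 for the hexosamine list, 0.013 for the unfolded protein response, 0.17 for extracellular matrix, 0.72 for atrial, 0.23 for fibroblast and 0.51 for macrophage markers.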

Other observations

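The tests of body weight, of blood glucose, of same-slide pairs and of a resemblance between the transgene and STZ were chosen only after the results were seen.

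Further lists were tested for STZ in CON, and those called by camera lost the call with an estimated correlation. Among 19 circadian clock genes Per2, a repressor of the clock, rose by 1.90 and Hlf, a clock output factor, fell by 0.48, and 2 rose and 1 fell when adjusted over the list alone. The clock list mean was 0.42 (adjusted p = 0.0431; adjusted p = 0.382 with an estimated correlation), 0.43 with slide as a block and 0.29, 0.49 and 0.48 within slides. Among 30 genes of antioxidant defence Gpx3, a plasma glutathione peroxidase, rose by 0.85 and Cat, catalase, by 0.70, while Gsta4, a glutathione transferase, fell by 0.39 and Prdx5, a mitochondrial peroxiredoxin, fell by 0.31. Prdx5 missed the threshold with slide as a block (adjusted p = 0.052). When adjusted over the list alone 9 rose and 4 fell, and the list mean was 0.30 (adjusted p = 0.0386; adjusted p = 0.551 with an estimated correlation). In fatty acid and sterol synthesis 3 of 25 genes rose, Scd4, a stearoyl-CoA desaturase, by 1.60, Elovl1, a fatty acid elongase, by 0.56 and Me1, malic enzyme, by 0.47, and the list was not called (adjusted p = 0.362). Pnpla3, a lipid droplet protein, changed by -1.31 on its brighter probe and by -0.12 on its other probe. Among 29 cell cycle genes Ccne1, cyclin E, changed by -1.18 and Cenpa, the centromeric histone, by -0.44, with a list mean of -0.27 (adjusted p = 0.00917; adjusted p = 0.551 with an estimated correlation). In glycogen metabolism 1 of 19 genes fell, Epm2a, the glycogen phosphatase laforin, by 0.50, with a list mean of -0.09 (adjusted p = 0.0431; adjusted p = 0.464 with an estimated correlation). Insulin signalling and FoxO targets had a mean of 0.34 (adjusted p = 0.00871; adjusted p = 0.512 with an estimated correlation) and mitochondrially encoded genes of -0.15 (adjusted p = 0.00917; adjusted p = 0.45 with an estimated correlation), with no member past limma's test. Skeletal muscle markers had a mean of -0.19 (adjusted p = 0.0144; adjusted p = 0.203 with an estimated correlation). The exact permutation test on array means passed for the clock (adjusted p = 0.0117) and antioxidant defence (adjusted p = 0.0206). It did not pass for insulin signalling (0.0659), glycogen (0.212), mitochondrially encoded genes (0.212), cell cycle (0.293) or skeletal muscle markers (0.419).

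Erythrocyte and platelet markers had a mean of -0.43 in CON (adjusted p = 0.0395; adjusted p = 0.436 with an estimated correlation), with Ppbp, a platelet chemokine, at -0.98, and a mean of -0.39 in mG4H (adjusted p = 0.0292; adjusted p = 0.671 with an estimated correlation). The CON mean passed the exact permutation test (adjusted p = 0.0117), with -0.47, -0.16 and -0.55 within slides. On slide 2 the mG4H value turned to 0.36, and an exact permutation test of the mG4H mean gave p = 0.47. Lymphocyte markers had a mean of -0.40 in CON (adjusted p = 0.0239; adjusted p = 0.436 with an estimated correlation) and of -0.58 in mG4H (adjusted p = 0.00107; adjusted p = 0.671 with an estimated correlation), with no member past limma's test. Neutrophil markers were not called, with means of 0.51 in CON (adjusted p = 0.0678) and 0.47 in mG4H (adjusted p = 0.275). Mesothelial and epicardial markers, which can vary with how much of the heart's surface a piece holds, had a mean of 0.97 in mG4H after STZ (adjusted p = 0.00423; adjusted p = 0.671 with an estimated correlation), with 1.57, -0.058 and 2.76 within slides. Gm4841, which lies outside the rule for names and was chosen after its values were seen, had a log2 fold change of -5.19 for STZ in mG4H (adjusted p = 0.00869) and was above background in 2 of 6 STZ mice.

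The third pattern is the spread of the STZ response among STZ mice, measured as the mean signed change over the 2908 genes of the mean STZ effect, 0.56 ± 0.17 (SD, n = 6) in CON and 0.47 ± 0.30 in mG4H. Slide differences are argued against, as the whole source, since 59.0% of the spread within groups lay between mice of the same group and slide. Blood glucose remains open, since the 3 mG4H STZ mice at 601 had scores of 0.38 to 0.95 and the 3 at 500 to 516 had 0.16 to 0.37 (exact permutation p = 0.1, the smallest that the 20 splits can give), only 1 slide held mice of both kinds, and CON STZ values of 600 and 601 allow no test. Body weight, picked after the scores of single mice and their glucose had been looked at, had a Pearson r of -0.80 (exact permutation p = 0.05) and a Spearman rho of -0.93 (exact p = 0.0167) in CON STZ, and an r of -0.66 (exact p = 0.165) and a rho of -0.37 (exact p = 0.497) in mG4H STZ; adjusted over these 4 relations and the glucose test p was 0.125, 0.0835, 0.206 and 0.497 for weight and 0.167 for glucose, and without the 2 weights farthest from the median r was -0.78 in CON STZ and 0.16 in mG4H STZ, where the relation rests on those mice. In 6 of 6 same-slide pairs the lighter mouse had the higher score (exact sign-flip permutation p = 0.0312, the smallest that 6 pairs can give), so lower weight, measured once per mouse with no starting value, may go with a stronger response, as a hypothesis from the same mice.

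A resemblance of the vehicle mG4H heart to the diabetic control heart was also tested, and none was seen across all genes. Of the 23 genes called for genotype under vehicle, 13 were also called for STZ in CON, 3 higher in both, 9 lower in both and 1 opposite, against 0.166 and 0.298 in equal direction by chance. Both contrasts share the CON VEH mice, which these chance counts do not take into account. The r of the effects across all genes was 0.26, below the 0.50 that 20 simulations without any effect gave from the shared mice alone. Those simulations held no STZ effect and used 1 spread per gene for all groups, so 0.50 is only a rough benchmark. With separate CON VEH mice for each contrast, over 20 divisions, r averaged -0.14, and -0.034 with slide as a block. Most genes were called in neither contrast, so this cannot exclude a resemblance limited to the genes called in both, which mostly moved in equal direction.

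Lower Klf15, a transcription factor that drives branched-chain amino acid breakdown, was tested as a possible source of the lower catabolism genes under vehicle. Its log2 fold change there was -0.483 ± 0.45 (SE, limma adjusted p = 1), too uncertain to tell, so this stays open.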
